A study of Homo sapiens with 8 samples.

How the data were processed

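RNA from PNT2 cells, an established line of immortalized human prostatic epithelium, was measured on Affymetrix human exon arrays. Per the labels' protocols, 1 µg of total RNA per sample was depleted of ribosomal RNA and converted to biotinylated sense-strand DNA before hybridization. There was 1 array per sample. Groups came from the sample titles: 4 arrays of cells transfected with small interfering RNA (siRNA) against ESRP1 and ESRP2 (siESRP) and 4 arrays of cells given siRNA against green fluorescent protein (siGFP), which serves as the control.

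The authors deposited a single table of linear intensity values with 18495 rows and 8 arrays. Each row is 1 transcript cluster, the array's unit for a gene. The background correction, the summary over probes and the scaling behind these intensities are not given in the sources used here. All values are whole numbers. Between 2.70% and 4.02% of rows per array lie below 0, as happens after background subtraction, and 353 rows lie below 0 on all 8 arrays. Array medians ran from 233 to 286, a range of 0.29 on the log2(value + 1) scale, so the arrays had not been brought to a common distribution. The deposited table holds 1 value per gene-level row, so exon inclusion was not measured from it, and no detection call was used. The number of arrays limits the precision, and a measured level near 0 cannot be told from background.

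The design fixed before the data were examined called for log2(value + 1) and for quantile normalization when log2 medians differ by over 0.1. Because values below 0 have no logarithm, arrays were quantile normalized on the linear scale, values below 0 were set to 0, and log2(value + 1) was taken. This floor was not foreseen in the design. Fold changes are on that log2(value + 1) scale and depend on the floor in dim rows, so where a group mean is under 50 the means are given in place of a fold. Means ± SD are quantile-normalized intensities. The test was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on all 8 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over all 18495 rows and a threshold of 0.05. All adjusted p-values of single genes are from this test.

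Gene names came from GEO's platform annotation, checked through Entrez IDs against the RefSeq gene table of GRCh38.p14. No genome build is named for the array values, so no coordinates are given. Of the rows, 14579 had 1 gene symbol, 2847 had several and 1069 had none. Rows with several symbols or none were tested and counted but are not named, except the row shared by ESRP2 and NFATC3. A gene with several rows was represented by its row with the highest mean, which gave 14272 genes.

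The rule for named genes was fixed in advance. It took ESRP1 and ESRP2, then the 12 highest and the 12 lowest log2 differences among called rows with 1 symbol and non-overlapping groups, and up to 4 genes with the smallest p from each gene list. The 12 lowest all had siESRP means under 50, so a second ranking was added after the data were seen. It is limited to bright rows, meaning rows whose higher group mean is at least 100 and whose 8 normalized values are all above 0. Other list members are named as examples or to complete a small count and were chosen after their values were seen.

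Besides the knockdown targets, 22 gene lists were fixed before the data were examined and tested with limma's camera. Of these, 21 are reported, and 1 entered the adjustment only and is not reported here. The 21 are reported ESRP splicing targets, epithelial junction and identity, mesenchymal and epithelial-mesenchymal transition (EMT), basal keratinocyte-type, luminal prostate, neuroendocrine, leukocyte and endothelial markers, interferon response, NF-kappaB and inflammatory genes, G2/M cell cycle, G1/S and DNA replication, replication-dependent histones, p53 targets, cholesterol biosynthesis, unfolded protein and amino acid response, TGF-beta response, Wnt and beta-catenin targets, splicing regulators, laminin, integrin and matrix adhesion, and growth factor ligands and receptors. Camera used a preset inter-gene correlation of 0.01, with adjustment over the 22 lists. An estimated correlation, camera on ranks and limma's fry were alternatives.

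Simulated data had 200 of 18495 rows changed, as many up as down and all at an intensity of at least 100. The same steps recovered 60 of 100 rows changed 1.5-fold and 87 of 100 changed 2-fold, and called 12 unchanged rows. With 3729 rows called in the real data, recovery there can differ. In a simulation over 14272 genes, camera called 0 of 21 unchanged lists, and called the p53 list when it was shifted by 0.5 on the log2 scale. The genes of a list were independent in this simulation.

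Alternatives were arrays as deposited, median scaling, leaving out the dimmest 25% of rows, a pseudocount of 16, a trended and robust eBayes, array weights, the replicate number as a block, thresholds of 0.01 or a 1.5-fold change, the mean over rows of a gene, and leaving out each array in turn. Restricting the test to bright rows was added after the data were seen.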

Results

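ESRP1 and ESRP2 are epithelial RNA-binding proteins that regulate splicing. The series compared PNT2 prostatic epithelial cells depleted of both with control cells. The gene-level values used here do not measure splicing. Expression arrays were available for 4 siESRP samples and 4 siGFP controls. Median deposited intensity was between 233 and 286 per array. After normalization, Spearman correlations were 0.988 to 0.994 within siGFP, 0.987 to 0.995 within siESRP and 0.978 to 0.985 between the groups. The labels do not say whether samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

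Both siRNA targets fell. The ESRP1 row dropped from 2439 ± 169 to 582 ± 66.9 (SD, n = 4 each), a reduction of 76.2% (log2 difference −2.07 ± 0.10 SE, limma adjusted p = 6.58e-05). The 4 siESRP values were 568, 499, 660 and 599, against 2232, 2527, 2617 and 2379 in siGFP. The row annotated to both ESRP2 and NFATC3 dropped from 531 ± 33.4 to 148 ± 27.4 (SD, n = 4 each), a reduction of 72.1% (log2 difference −1.85 ± 0.14 SE, limma adjusted p = 0.000336). A separate row for NFATC3 alone was 635 ± 44.3 in siGFP and 596 ± 33.8 in siESRP (limma adjusted p = 0.403). Both target rows had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give. By the labels, quantitative RT-PCR put the knockdown close to 80%.

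**Figure D1:**
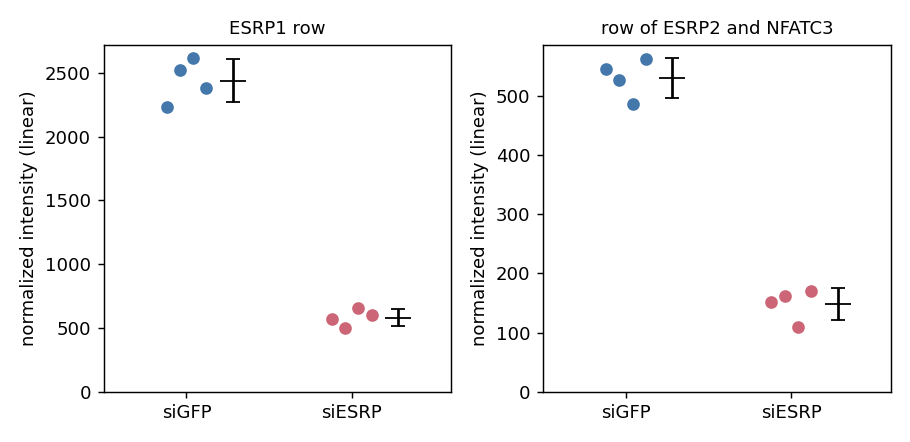
Normalized linear intensity of the ESRP1 row (left) and of the row shared by ESRP2 and NFATC3 (right) on each array; points are arrays, horizontal marks are means and bars are SD, n = 4 per group. The siESRP means are 582 against 2439 for ESRP1 and 148 against 531 for the shared row, with no overlap between groups.

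Beyond the targets, 3729 of 18495 rows differed between siESRP and siGFP (limma, adjusted p under 0.05). Of these, 2007 were higher in siESRP and 1722 were lower. With a change of at least 1.5-fold, 866 were higher and 443 lower, and at 2-fold, 270 were higher and 87 lower. The groups did not overlap in 3662 of the called rows and in 24.6% of all rows, where chance gives 2.86%. The median log2 difference over all rows was −0.02 after quantile normalization, −0.10 on the deposited scale and −0.11 with median scaling. On the deposited scale, where array medians differ, 1045 rows were higher and 628 lower, and with median scaling 1538 were higher and 1519 lower (725 and 532 with at least 1.5-fold).

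Among the largest increases of bright rows, TP53INP1, a p53-induced stress gene, rose from 40.8 ± 7.48 to 441 ± 71.8 (SD, n = 4 each, adjusted p = 7.91e-05). KRTCAP2, a subunit of the oligosaccharyltransferase that N-glycosylates proteins, rose 8.80-fold from 529 ± 66.7 to 4657 ± 510. ABCA12, a lipid transporter of the skin, rose 6.70-fold, and AHNAK2 rose 6.50-fold. INPP5D, an inositol phosphatase best known from blood cells, rose 5.38-fold, STAT6, the transcription factor of IL-4 signalling, rose 5.32-fold, and BLNK, a B-cell adaptor, rose from 47.6 to 225. CYFIP2 rose 4.71-fold and VTCN1, an inhibitory immune ligand, 4.71-fold. CLCA2, DNAI3 and TMCC3 rose from siGFP means near background, 23.6, 23.0 and 10.6, to 144, 145 and 112, so their place in the ranking is uncertain.

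The largest decrease among bright rows was that of OLR1, the receptor for oxidized low-density lipoprotein, which fell 4.82-fold from 2060 ± 83.5 to 428 ± 32.1 (SD, n = 4 each, adjusted p = 2.11e-05). YARS1, the cytosolic tyrosyl-tRNA synthetase, fell 4.69-fold from 2206 ± 170 to 470 ± 48.8. ESRP1 came next. MYL9, a myosin light chain of contractile cells, fell 3.60-fold, ZNF385B from 140 to 42.3 and the antiviral gene RSAD2 3.19-fold. SCG2 fell 3.08-fold, DACT1 3.04-fold, SH3RF2 2.92-fold, LBH 2.87-fold, the cytokine gene LTB 2.76-fold and C4BPB 2.66-fold. Each of these 24 genes passed the limma threshold, with adjusted p of at most 0.00830.

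The ranking fixed in advance, over all rows, was led by rows near background. Its 12 highest were ICAM5, TMCC3, TP53INP1, SERPINB9P1, TEX13A, KRTCAP2, BTG4, ABCA12, AHNAK2, DNAI3, STARD6 and CLCA2, of which 9 had siGFP means under 50. Its 12 lowest were TSEN34, BATF3, LINC01101, MYO15A, MUTYH, FAM223A, GFRA4, TFF2, CYSLTR2, CYP2R1, OR2B6 and CMTM2. In all 12 both group means were under 50, and in 10 the siESRP mean was below 0, so no fold is given for these.

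The p53 target list shifted up. Of 21 measured p53 targets, 15 rose, 0 fell and 6 did not pass (17 rose when adjusted over the list alone). MDM2, the ligase that degrades p53, rose 2.76-fold from 1047 ± 206 to 2852 ± 199 (SD, n = 4 each). CDKN1A, the cell-cycle inhibitor p21, rose 2.04-fold. RRM2B, a ribonucleotide reductase subunit, rose 3.03-fold, the death receptor FAS 2.85-fold, ZMAT3 2.89-fold, SESN1 2.59-fold, the DNA repair gene DDB2 1.94-fold and the polymerase POLH 1.54-fold. The log2 differences of BAX (0.18) and GADD45A (−0.03) did not pass. The list median was 0.73 on the log2 scale (camera adjusted p = 8.79e-11; adjusted p = 0.00971 with an estimated correlation).

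Genes for matrix and matrix attachment also shifted up. Of 34 measured genes of the laminin, integrin and matrix adhesion list, 22 rose and 1 fell (23 and 2 adjusted over the list alone). The laminin chain LAMA4 rose 2.40-fold, the basement-membrane collagen COL4A5 2.19-fold and the integrin ITGB8 1.99-fold. The plasminogen activators PLAU and PLAT rose 2.21-fold and 2.10-fold, and ITGB1, the common integrin beta chain, rose 1.29-fold. The gene that fell was MMP3, from 42.8 ± 2.88 to 15.8 ± 6.45. The list median was 0.38 (camera adjusted p = 7.52e-11; adjusted p = 0.0201 with an estimated correlation).

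More epithelial genes rose than fell. Of 39 measured epithelial junction and identity genes, 14 rose and 3 fell (17 and 7 adjusted over the list alone). CDH1, which encodes E-cadherin, rose 1.42-fold from 2137 ± 126 to 3042 ± 168 (SD, n = 4 each), and CDH3, P-cadherin, rose 1.65-fold. The desmosomal cadherins DSC3 and DSG3 rose from 27.0 to 96.7 and from 47.4 to 132. The 3 that fell were the plakophilin PKP3 by 1.57-fold, TJP1 by 1.21-fold and GRHL1 by 1.20-fold. EPCAM (log2 difference −0.11) did not pass. The list had camera adjusted p = 0.0229, with adjusted p = 0.134 with an estimated correlation.

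Mesenchymal genes went both ways: of 35 measured, 8 rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.487). The list median was 0.01. The list mean ran from 0.05 to 0.17 over the siESRP arrays and from −0.01 to 0.01 over the siGFP arrays (exact two-sided permutation p = 0.0286). CDH2, which encodes N-cadherin, fell 2.06-fold from 1295 ± 42.4 to 631 ± 61.3. FAP, a membrane protease of activated fibroblasts, rose 4.11-fold, the membrane metalloproteinase MMP14 from 33.8 to 121, and the basement-membrane protein NID1 2.41-fold. VIM, which encodes vimentin, rose 1.21-fold at an intensity below 200. The EMT transcription factors ZEB1 (−0.23), SNAI1 (0.12) and SNAI2 (−0.14) did not pass, nor did ZEB2, with both means near 29.4.

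Both prostate epithelial marker lists had positive medians. The basal list holds 18 genes, of which only 8 had a row with 1 symbol and were measured. Of these 8, 3 rose and 1 fell (5 and 1 adjusted over the list alone). The integrin ITGA3 rose 1.84-fold, ITGA6 1.30-fold and KRT15 1.53-fold, and KRT14 fell 2.06-fold. KRT14 has close paralogues, among them KRT16 and KRT17, so its value is uncertain. Of 13 luminal markers, 5 rose and 0 fell (5 and 1 adjusted over the list alone), including STEAP2 by 2.68-fold, NDRG1 by 1.85-fold, KRT18 by 1.22-fold and KRT19 by 1.17-fold. Camera gave adjusted p = 0.0369 for basal and 0.0311 for luminal markers, and adjusted p = 0.176 for both with an estimated correlation. Without siGFP replicate 2 both calls ended (adjusted p = 0.0775 and 0.0529), and the basal call also ended without siGFP replicate 4 (0.0559) or siESRP replicate 3 (0.0681).

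Growth factor genes tended upward. Of 43 measured ligands, receptors and feedback genes, 11 rose and 3 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.0131; adjusted p = 0.176 with an estimated correlation). The EGF-family ligands TGFA, EREG, BTC and HBEGF rose 1.94-fold, 1.64-fold, 1.54-fold and 1.21-fold. FGFR1 rose 1.87-fold, EFNB1 1.69-fold and DUSP6, a phosphatase induced by ERK signalling, 1.95-fold. EGFR itself fell 1.19-fold from 2572 ± 167 to 2169 ± 150.

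Interferon-induced genes shifted down. Of 33 measured, 17 fell and 1 rose (20 and 2 adjusted over the list alone). RSAD2 fell 3.19-fold, ISG15, a ubiquitin-like modifier, 2.21-fold, OAS3, a sensor of double-stranded RNA, 1.99-fold, the RNA sensor IFIH1 1.69-fold and IFITM1 1.58-fold. TRIM22, which is also reported as a p53 target, was the gene that rose, by 3.22-fold. The list median was −0.34 (camera adjusted p = 8.63e-06; adjusted p = 0.202 with an estimated correlation). The mean log2 change of the list ran from −0.53 to −0.24 over the siESRP arrays and from −0.03 to 0.06 over the siGFP arrays (exact two-sided permutation p = 0.0286).

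**Figure D2:**
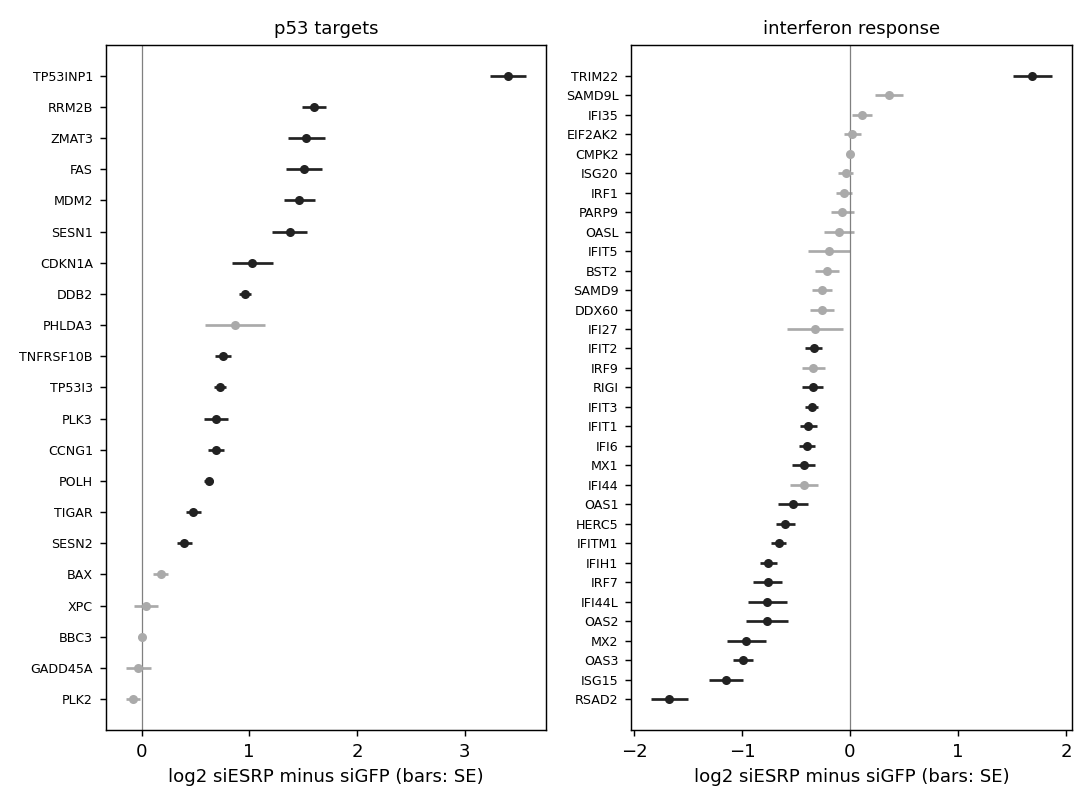
Log2 difference siESRP minus siGFP of each measured p53 target (left) and interferon response gene (right); points are limma estimates, bars are SE, black marks adjusted p under 0.05 and grey the rest. Of the p53 targets 15 rose and 0 fell, and of the interferon genes 17 fell and 1 rose; BBC3 and CMPK2 were at the floor in both groups.

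Of 30 measured G2/M genes, 10 fell and 0 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00312; adjusted p = 0.176 with an estimated correlation). CCNB2, a mitotic cyclin, fell 1.74-fold, AURKB 1.33-fold, the proliferation marker MKI67 1.28-fold and UBE2C 1.18-fold. On the deposited scale the list's adjusted p was 0.0520. CDK1 (0.05), CCNB1 (0.00) and TOP2A (−0.09) did not pass. Of 30 G1/S and replication genes, 5 rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.901). TYMS, the thymidylate synthase, rose 1.58-fold, and PRIM1, CDT1 and CDC25A fell 1.38-fold, 1.29-fold and 1.27-fold. Of 11 measured histone genes only H3C2 passed, 1.35-fold lower, and 0 passed adjusted over the list alone (camera adjusted p = 0.188). Histone genes are near-identical copies, so these values are uncertain; H2AC6, H4C3 and H4C8 had log2 differences of −0.35, −0.35 and −0.37 without passing.

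Inflammatory genes leaned down without a call of the list. Of 20 NF-kappaB and inflammatory genes, 6 fell and 2 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.121): the chemokine CCL20 fell from 76.6 to 40.4, CXCL8 fell 1.57-fold, and NFKB1 and RELB fell 1.28-fold and 1.31-fold.

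Of 21 measured TGF-beta response genes, 6 rose and 7 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.875). The activin subunit gene INHBA fell 2.24-fold, the matrix protein THBS1 1.69-fold and PMEPA1 1.70-fold, and LTBP2 rose 1.69-fold. Of 26 unfolded protein and amino acid response genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.875). ASNS, the asparagine synthetase, fell 1.96-fold, and the cystine transporter genes SLC7A11 and SLC3A2 fell 1.65-fold and 1.44-fold. EDEM1, of endoplasmic reticulum degradation, rose 2.00-fold. Of 15 cholesterol synthesis genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.120), with MSMO1 up 2.37-fold, STARD4 1.54-fold, SC5D 1.53-fold and TM7SF2 1.48-fold. Of 14 Wnt targets, DKK1 rose 1.48-fold and CCND1 1.21-fold, and TNFRSF19 (0.22) and CD44 (0.06) did not pass (2 higher adjusted over the list alone; camera adjusted p = 0.307).

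Genes reported to be spliced by the ESRPs went both ways in their gene-level rows, which do not measure splicing. Whether changed exon use itself moved these rows, or any other row, was not tested. Of 17 measured, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.334). FGFR2, the receptor whose exon choice the ESRPs control, rose 1.40-fold from 131 ± 8.92 to 184 ± 19.4, RALGPS2 rose 1.40-fold and OSBPL3 1.19-fold, and ENAH and GRHL1 fell 1.33-fold and 1.20-fold. Part of this list was reported from work on these same cells, so it is not independent evidence. Of 38 splicing regulators, 3 rose and 2 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.875). RBFOX2 rose 1.27-fold, HNRNPLL 1.31-fold and HNRNPF 1.14-fold, and PTBP1 fell 1.15-fold.

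Few single markers of other cell types passed. Of 10 neuroendocrine markers only SCG2 passed, 3.08-fold lower, while ENO2 (0.27) did not, nor did SCG3 (means of 5.72 and 1.94) and CALCA (30.6 and 21.4), both near background (1 lower adjusted over the list alone; camera adjusted p = 0.474). The list median was −0.15. The list mean, drawn down mainly by SCG2 and the near-background SCG3, ran from −0.45 to −0.23 over the siESRP arrays and from −0.09 to 0.05 over the siGFP arrays (exact two-sided permutation p = 0.0286). Of 10 leukocyte markers only CSF1R passed, 1.88-fold lower. LCP1, CD3E and PTPRC had intensities under 30 in both groups (1 lower adjusted over the list alone; camera adjusted p = 0.875). Of 11 endothelial markers CDH5 rose 1.34-fold and TEK fell with both means under 50, and EMCN and PECAM1 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.901).

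**Figure D3:**
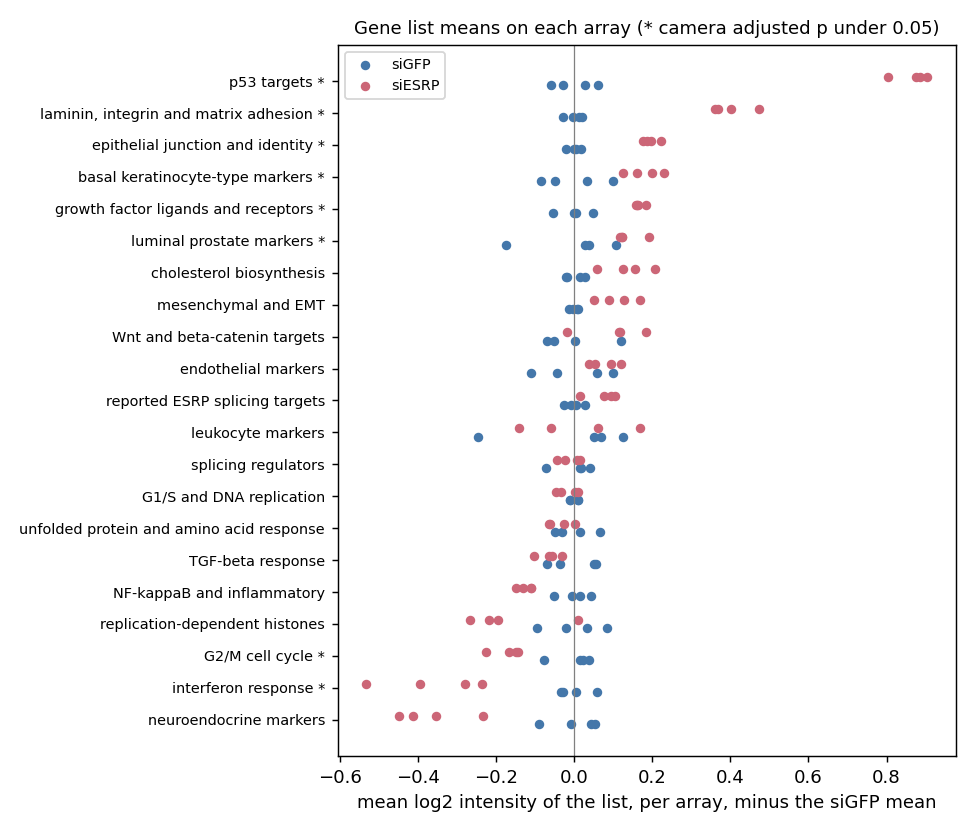
Mean log2 intensity of each gene list on each array, minus the siGFP mean of that list (horizontal axis, log2 units); points are arrays, blue siGFP and red siESRP, and asterisks mark camera adjusted p under 0.05. The p53 list lies between 0.80 and 0.90 on the siESRP arrays and the interferon list between −0.53 and −0.24.

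Median, mean and test differed in sign for 6 lists without a call. These were G1/S and replication (median 0.02, mean −0.02, camera down), TGF-beta response (0.08, −0.06, down), unfolded protein response (0.05, −0.04, up), splicing regulators (0.01, −0.01, up), leukocyte markers (−0.01, 0.01, down) and endothelial markers (0.01, 0.08, down).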

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

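The rows of the ranking limited to bright rows were chosen for this test after the data were seen. Within each group of 4 arrays, 1 array stood apart from the other 3 by a gap ratio above Dixon's 95% critical value in 16 of 246 groups of values tested, where chance gives about 1 in 20, or 12.3. In siGFP these were EFNB1 (ratio 0.965, replicate 1 high), FGFR2 (0.832, replicate 3 high), CALCA (0.842, replicate 3 low) and KRT19 (0.861, replicate 3 low). In siESRP they were KRT19 (0.917, replicate 1 low), TM7SF2 (0.886, replicate 2 high), H3C2 (0.893, replicate 3 high), SLC3A2 (0.860, replicate 3 low) and BLNK (0.893, replicate 4 low). CALCA and the other 7 were rows near background. ICAM5 and SERPINB9P1 in siGFP, and FAM223A, LINC01101 and TFF2 in siESRP, had a ratio of 1 because the other 3 arrays were at the floor, and CMTM2 and TSEN34 in siESRP had ratios of 0.960 and 0.963. No array held more than 3 of the 16.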

How the results depend on the processing

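The alternatives followed the fixed lists, the shared ESRP2 row and the genes picked by both rankings and by the list rule. None of these changed direction while past its threshold under any alternative run. Directions of the other called rows, of list members named as examples and of the gene lists added later were not followed. The number of called rows was 3729 as reported and ran from 2719 to 3793 when 1 array was left out. It moved by over 1.5 times in 4 settings. On the deposited scale 1673 rows were called (1045 higher, 628 lower), of which 1565 were also called in the reported test. At adjusted p under 0.01 it was 1808 (1115 higher, 693 lower). With at least 1.5-fold it was 1309 (866 higher, 443 lower). With the replicate number as a block it was 2292, with 946 lower, and 2193 of these were shared. The samples share only a number: deviations from the group means correlated at 0.29, 0.06, −0.06 and −0.02 for replicates 1 to 4, and 1 of the 4 siGFP arrays correlated best with its own number. The block ended or created no list call. Of the 21 reported lists 8 were called as reported, 5 on the deposited scale, 5 on ranks, 2 with an estimated correlation, 15 with fry, and between 6 and 8 when 1 array was left out. With an estimated correlation the calls lost were epithelial junction (adjusted p = 0.134), basal, luminal, G2/M and growth factor (each 0.176) and interferon (0.202). On the deposited scale they were basal and luminal (each 0.0589) and G2/M (0.0520), on ranks epithelial and luminal (each 0.0602) and basal (0.0737), and with array weights basal (0.0533) and luminal (0.0507). The basal list also lost its call without the dimmest 25% of rows (0.0785) and with epithelial junction when only bright rows were used, an alternative chosen after seeing the data (0.0930 and 0.0728). Leaving out 1 array, adjusted p ran from 0.0255 to 0.0775 for basal and 0.0224 to 0.0529 for luminal. Fry, which does not compare a list with other genes, also called ESRP splicing targets (0.0484), mesenchymal (0.00401), neuroendocrine (0.0298), NF-kappaB (5.81e-05), cholesterol (0.000160), TGF-beta (0.0298) and Wnt genes (0.00824). Over pairs of a setting and a followed gene, targets aside, a call was lost in 120 and gained in 19, against 1744 unchanged. The cause of these changes was not tested, except that the stricter thresholds call fewer rows by construction. Signal over background limits dim rows: both group means were under 50 in 135 of the 3729 calls and 49 of those with at least 2-fold.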

Other observations

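Tests in this part on normalization, on single arrays, on the neighbours of KRTCAP2 and on splits by the number of arrays exchanged were chosen after the results were seen, and the 4 additional gene lists were drawn up after single genes had been seen. YARS1 was among the largest decreases, and the other cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were then tested. Of 17 measured, 4 fell and 1 rose: FARSA fell 1.37-fold, SARS1 1.34-fold, GARS1 1.32-fold and AARS1 1.20-fold, and QARS1 rose 1.39-fold (median log2 difference −0.14, camera p = 0.0153, adjusted over the 4 lists 0.0306, and adjusted p = 0.0923 with an estimated correlation, which ends the call). ASNS, CHAC1, TRIB3 and DDIT3, known targets of the amino acid response, also fell, by 1.96-fold, 2.13-fold, 1.59-fold and 1.48-fold, while the fixed list they belong to went both ways (6 rose and 6 fell of 26, camera adjusted p = 0.875). ANKRD1, a target of YAP and TEAD, had fallen 2.58-fold, so 18 other measured targets of these factors were tested, and 6 rose and 4 fell. Limma camera gave adjusted p = 0.933 for this list. CCN2 fell 1.59-fold and NUAK2 1.63-fold, while F3 rose 1.82-fold and MYOF 1.70-fold. The cilium genes CFAP91, STK36, CFAP69 and FANK1 had risen from siGFP means of 49.3, 166, 51.1 and 128 to 141, 430, 120 and 295, so 43 other motile cilium genes were tested. Of these 5 rose and 1 fell (limma camera p = 0.0508, adjusted p = 0.0677, and adjusted p = 0.414 with an estimated correlation): HYDIN rose 1.61-fold, RFX2 1.46-fold and CFAP44 1.40-fold, DNAAF11 and DNAH7 rose from siGFP means of 38.6 and 38.3, and DNAI2 fell with both means under 50.

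Relabelling the arrays gave 35 splits into 4 and 4. Only 1 of the 35, the real one, called as many as 3729 rows, and the highest other split called 3. This argues against chance for that count without excluding it, since 1 of 35 is the smallest possible share. The splits also take the arrays as independent, which the labels do not show. At least 8 lists were called by 2 of 35 splits, the real one with 8 and another with 9. That other split is 1 of 16 that exchange 1 array per group and so keep 0.5 of the group difference, and these 16 called between 2 and 9 lists. The 18 splits that exchange 2 arrays per group keep none of it, and they called at most 1 list. In them a real group difference adds to the spread within groups, which lowers the test statistics. Few calls and larger p are then likely, so these splits are no reference free of the effect. By camera p, the real split alone reached its value for p53 targets (1 of 35, 7.99e-12 against a smallest other p of 8.59e-07). The same held for laminin, integrin and matrix adhesion (1 of 35, 3.42e-12 against 2.86e-07). This argues against chance for these lists without excluding it. A share of 1 of 35 is the smallest possible and was not adjusted over the lists. For the other 6 lists a p as small came also from splits that exchange 1 array per group: epithelial junction (2 of 35, 0.00625 against 0.00390), luminal (2 of 35, 0.00988 against 0.00668), basal (3 of 35, 0.0134 against 0.00317), interferon (3 of 35, 1.18e-06 against 8.26e-08), G2/M (4 of 35, 0.000567 against 1.16e-06) and growth factor genes (4 of 35, 0.00297 against 0.000253). Those splits carry part of any real difference and can hide one, so these counts of 2 or more leave chance open without showing it. None of the 18 splits without it reached the real p of any of these lists, under the limit given above. Their smallest p was 0.189 for epithelial junction, 0.275 for luminal, 0.127 for basal, 0.00492 for interferon, 0.00381 for G2/M and 0.0772 for growth factor genes. Taken alone with the real split, these 18 are too few for a share under 0.05.

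For the rise of the p53 targets, between-array normalization is argued against, since the list median was 0.70 on whichever of the deposited and median scales gave the lower value, and so is a single array, since the highest adjusted p without 1 array was 1.24e-09. A second list of p53 targets that shares no gene with the first, and leaves out those seen among the largest changes, was also higher: 27 of 62 rose and 1 fell (median 0.34, camera p = 1.49e-09, adjusted p = 5.98e-09, and adjusted p = 0.0196 with an estimated correlation). These values are consistent with a p53-type response in siESRP cells, as a hypothesis. PNT2 cells were immortalized with SV40, whose large T antigen binds p53, so whether p53 itself acted is open, and depletion of p53 along with the ESRPs, which would test it, was not analysed here. An effect of the siRNA other than loss of the ESRPs cannot be told apart from the knockdown, because the labels tell only 1 siRNA treatment against ESRP1 and ESRP2 apart.

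Normalization is argued against as the whole source of the interferon fall (list median −0.34 as reported and −0.35 on the deposited or median scale, whichever lay nearer 0). All rows together had a median of −0.02 as reported, −0.10 on the deposited scale and −0.11 with median scaling. Part of the list's fall on the deposited and median scales is thus shared with all rows. Camera adjusted p was 8.63e-06 as reported, 0.000180 on the deposited scale and 0.000149 with median scaling. The list means of the groups did not overlap (exact two-sided permutation p = 0.0286, the smallest possible). That alone leaves variation between arrays unrelated to the groups open. The group means of 12 of 21 lists did not overlap, 4 of them without a camera call. Those 4 were the mesenchymal, neuroendocrine, NF-kappaB and cholesterol lists. The interferon camera call is lost with an estimated correlation (adjusted p = 0.202). Of the 35 splits 3 gave a camera p as small, the real one and 2 that keep 0.5 of the group difference. Of the 18 splits that keep none, 0 did, under the limit given above for such splits. A candidate explanation is that the control siRNA raised interferon genes in the siGFP cells, which cannot be told apart from a fall in siESRP cells because there were 0 untransfected arrays.

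KRTCAP2 rose 8.80-fold at high intensity. Its neighbours did not rise with it. TRIM46 and MUC1, the next 2 genes on one side in the RefSeq table, had log2 differences of −0.39 ± 0.20 and 0.24 ± 0.16 (SE). DPM3, the next protein-coding gene on the other side, fell 1.43-fold. Transcription running in from a neighbour stays open, because it need not raise the level of the neighbour itself. Normalization is argued against, since the log2 difference on the deposited scale was 3.16. A direct or indirect effect of either siRNA stays open as untested, and so does changed exon use within the KRTCAP2 row.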
